A study of Rattus norvegicus with 18 samples.

How the data were processed

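Kidney tissue of rats was profiled by RNA sequencing after depletion of ribosomal RNA, per the labels' protocols. The labels give 18 libraries in 3 groups of 6: Wistar-Kyoto rats (WKY) on water, spontaneously hypertensive rats (SHR) on water, and SHR given isoliensinine at 5 mg/kg per day (SHR+Iso), each for 10 weeks. Replicate numbers come from the labels. The labels list the libraries as separate samples of a group, and the design text gives 6 rats' kidneys per group, so p-values measure the spread between these samples.

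Each deposited file holds 1 value per transcript for 1 library, a normalized signal that the authors computed on a scale the files do not state. The values are never negative and are not whole at low levels, as FPKM or TPM values would be, and they are called values below. The submitters' processing notes name limma, without a version. The aligner, the quantifier, the genome build and the annotation are not given in the sources used here. Sequencing depth is unknown, so no counting interval or detection floor was computed. An exact 0 in such a file can be a failed estimate, and transcripts are described as listed at 0.

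The files hold part of the transcriptome. The WKY and SHR files list the same 4005 transcripts and the SHR+Iso files list the same 2823, with 614 in common. Sums of values over these lists are therefore not library totals. The listed transcripts were selected on the differences under study. With an offset of 0.01, 99.4% of the 4005 differed between SHR and WKY by at least 1 on the log2 scale, and no higher group mean lay below 0.500. Among the shared 614, 98.9% differed by at least 1 between SHR+Iso and SHR, and no higher group mean lay below 0.503. Numbers of transcripts past a threshold, their share of those tested, and opposite directions in the strain and treatment comparisons follow in part from this selection. The p-values, also those of named transcripts, were computed on these selected lists and adjusted over them alone. They give no error rate over the transcriptome. The SHR+Iso libraries were compared with the other groups over the shared 614 alone.

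Transcripts are named by Ensembl transcript IDs or by IDs of a merged assembly (MERGE, a locus number and an isoform number). The files do not pair them with gene names. Of the 6214 IDs, 0 matched the gene table available for rat (assembly GRCr8), so genes, chromosomes and exons are not given. The 43 gene lists fixed before the data were examined hold 699 symbols, of which 0 matched, and neither the list tests nor the genes fixed by name were run. These lists covered TGF-beta and SMAD genes, matrix genes, markers of kidney and other cell types, and RNA quality. The rule for named items took, per comparison, the largest rises and falls among transcripts past the threshold whose 6 and 6 values did not overlap and whose mean level lay above the 25th percentile of those tested. It was limited to 2 IDs per direction because no names could be given, and was applied to the strain and the treatment comparisons.

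Each comparison was fitted on its own 12 libraries with limma 3.58.1 in R 4.3.3, with a trended prior and robust estimation, on log2(value + 1). Transcripts needed a value of at least 1 in at least 6 of the 12 libraries. P-values were two-sided and Benjamini-Hochberg adjusted over the transcripts tested, with a threshold of 0.05. Unless another offset is given, log2 differences are on the log2(value + 1) scale, which understates changes of low transcripts. The design fixed before the data were examined gave this test for normalized values and others for counts. The values were treated as normalized although their scale is not stated. No library was left out of the main comparisons.

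The strain and treatment comparisons share the SHR libraries. Chance opposition was estimated from 200 simulations of unchanged groups, from the product of independent lists, and by splitting the SHR libraries. Alternatives were quantile normalization, no filter, a filter at 5, a fit without trend, a pseudocount of 0.1, 1 fit over all 3 groups, the replicate number as a block, each library left out in turn, and a log2 difference of at least 1. Leaving out SHR+Iso replicates 2 and 4 together, or each pair of treated libraries, was added after seeing the data, as were the numbers of transcripts listed at 0 throughout 1 strain.

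The test was checked on simulated data. For SHR against WKY, with 1657 transcripts, it recovered 59% of changes of 1 on the log2 scale and 83% of changes of 2, and 4.05% of its calls were false. For SHR+Iso against SHR, with 289 transcripts, it recovered 30% and 90%, and 10% of its calls, 4 in number, were false, above the nominal rate. For SHR+Iso against WKY, with 255 transcripts, it recovered 26.7% and 80%, with 5.88% false. Each comparison was simulated in a single draw. In these draws 200 of the 1657, 60 of the 289 and 60 of the 255 transcripts were changed, and none was selected on the groups. The rates therefore do not carry over to calls from the selected lists. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.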

Results

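Kidney transcripts were measured in 3 groups of 6 rats. WKY is the normotensive Wistar-Kyoto strain, and SHR is the spontaneously hypertensive rat, used as a model of essential hypertension. The third group, SHR+Iso, was SHR treated with isoliensinine, a bisbenzylisoquinoline alkaloid of lotus seed, at 5 mg/kg per day. All groups were followed for 10 weeks, and the series title places the work in renal injury and TGF-β1/SMAD2/3 signalling. The values are the authors' normalized transcript abundances, whose scale and depth are unknown, for lists of transcripts already selected for differing between groups.

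The WKY and SHR libraries listed 4005 transcripts, 828 with Ensembl IDs and 3177 from a merged assembly. Their values summed to 16176.6 to 18095.8 per WKY library and to 15382.3 to 17937.5 per SHR library. Between 708 and 1037 transcripts were listed at 0 in a WKY library, and between 771 and 971 in an SHR library. The SHR+Iso libraries listed 2823 transcripts, 658 with Ensembl IDs, with sums of 9075.44 to 11600.9. Replicates 2 and 4 of this group had 1018 and 906 transcripts listed at 0, against 455 to 644 in its other 4 libraries. Correlations between replicates across transcripts, on the log2 scale, were 0.700 to 0.805 in WKY, 0.753 to 0.827 in SHR and 0.542 to 0.749 in SHR+Iso. Over the 614 transcripts listed for all groups, the median SD was 0.40 in SHR, 0.49 in WKY and 0.56 in SHR+Iso on the log2 scale.

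The comparison of SHR with WKY on water asks how the kidney differs between the strains. Hypertension and genetic background differ together in this design and cannot be told apart. Several abundant transcripts were listed for one strain and at 0 in the other. The assembled transcript MERGE.22775.1 had values of 53.2 ± 6.13 (SD, n = 6) in SHR and was listed at 0 in all 6 WKY libraries (limma adjusted p = 3.18e-10). MERGE.22207.1 had 58.3 ± 30.8 (SD, n = 6) in SHR and was likewise listed at 0 in all 6 WKY libraries (limma adjusted p = 1.04e-08). In the other direction, ENSRNOT00000049573 had 72.9 ± 22.6 (SD, n = 6) in WKY and MERGE.19286.4 ranged from 24.6 to 252.3 there, and both were listed at 0 in all 6 SHR libraries (limma adjusted p = 1.34e-09 and 1.44e-06). None of these 4 transcripts was listed for the SHR+Iso libraries, which does not show that they were absent there.

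In a description chosen after seeing the data, 87 transcripts were above 0 in all 6 SHR libraries and listed at 0 in all 6 WKY libraries, 7 of them with Ensembl IDs. Their median SHR mean was 1.18, and 11 had a mean of at least 10. The reverse held for 121 transcripts, again 7 with Ensembl IDs, with a median WKY mean of 1.69 and 11 at a mean of at least 10. Of the 87 SHR transcripts, 14 were also listed for SHR+Iso, and all 14 were above 0 in at least 1 treated library, 3 of them in all 6. Of the 121 WKY transcripts, 1 was listed for SHR+Iso, and it was above 0 in replicates 1, 5 and 6. Of all 4005 transcripts, 614 were listed for SHR+Iso. The SHR+Iso list was itself selected, so a transcript missing from it was not shown to be absent in treated rats.

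Of the 4005 transcripts, 1945 had a higher mean in SHR and 2060 a higher mean in WKY. Of the 1657 tested with limma, 1368 passed an adjusted p of 0.05, 647 higher and 721 lower in SHR, and 1429 had an unadjusted p under 0.05. The median log2 difference was 1.23 among those higher and -1.22 among those lower. Among Ensembl transcripts 202 were higher and 187 lower, and among assembled transcripts 445 were higher and 534 lower. The 6 and 6 values did not overlap for 1135 of the 4005, or 28.3%, where chance gives 0.216%. These shares describe a list selected for strain differences, not the kidney transcriptome. The number of calls was 3102 without a filter on low values, 404 with a filter at 5, and 213 in 1 fit over all 3 groups, which holds only the shared transcripts.

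**Figure D1:**
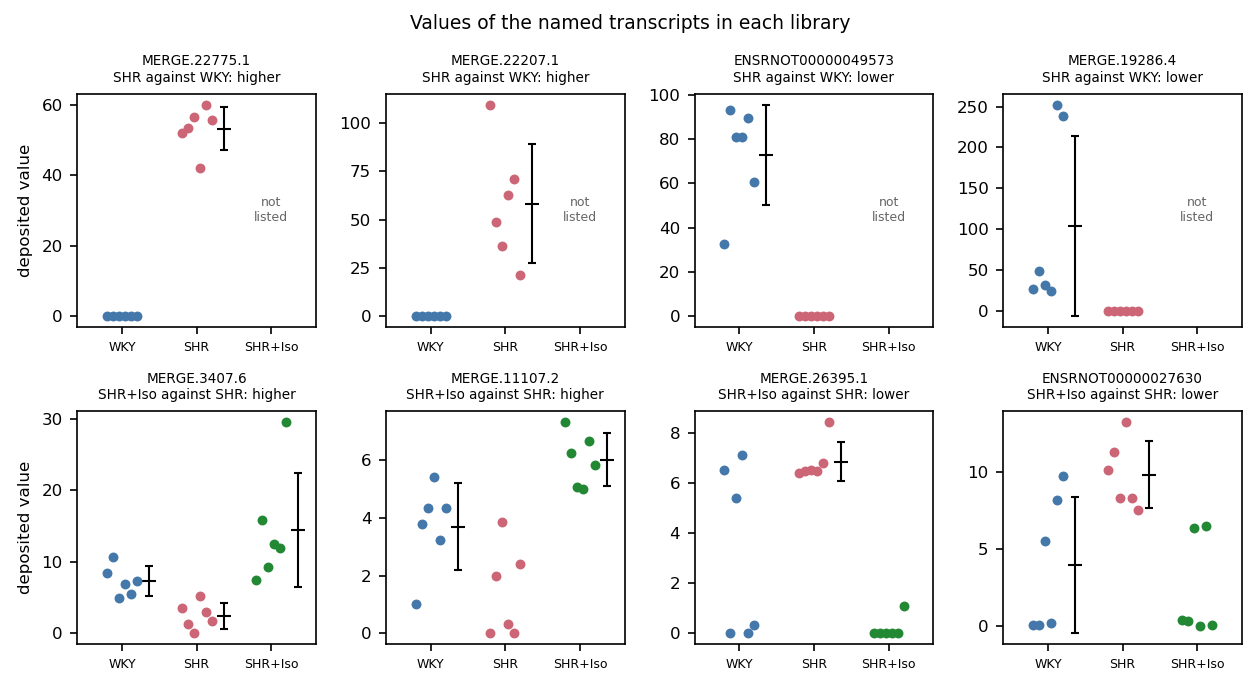
Deposited value (vertical axis, normalized abundance of unstated scale) of each named transcript in each library, 1 point per library, 6 per group. Black bars give the mean and SD of groups with no library at 0. The top panels show transcripts listed at 0 in all 6 libraries of 1 strain and not listed for SHR+Iso, and the bottom panels show transcripts that differed between SHR+Iso and SHR.

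The comparison of treated with untreated SHR asks what isoliensinine changed. MERGE.3407.6 was higher in SHR+Iso, at 14.4 ± 7.95 against 2.46 ± 1.82 (SD, n = 6 each), a log2 difference of 2.23 ± 0.51 (SE; limma adjusted p = 0.00707). Its WKY value was 7.32 ± 2.09 (SD, n = 6). MERGE.11107.2 was at 6.02 ± 0.913 (SD, n = 6) in SHR+Iso, while its SHR values were 0, 1.98, 3.86, 0.341, 0 and 2.40 (limma adjusted p = 0.00914). MERGE.26395.1 was lower after treatment, at 6.85 ± 0.788 (SD, n = 6) in SHR. It was listed at 0 in SHR+Iso replicates 2, 4 and 5 and at 0.0188, 0.0129 and 1.07 in replicates 1, 3 and 6 (limma adjusted p = 1.07e-05). In WKY, MERGE.26395.1 was at 6.52, 5.40 and 7.10 in replicates 1, 3 and 4 and at 0.0124, 0 and 0.346 in replicates 2, 5 and 6. ENSRNOT00000027630 was at 9.81 ± 2.18 (SD, n = 6) in SHR, while its SHR+Iso values were 0.382, 0.321, 6.36, 0, 6.47 and 0.00703 (limma adjusted p = 0.00914). Its WKY values were 0.0206, 0.00609, 5.49, 0.195, 8.17 and 9.72, so low values also occurred in untreated rats. Without SHR+Iso replicates 2 and 4, chosen after seeing the data, its limma adjusted p was 0.0545 and its log2 difference -1.85; over all settings its adjusted p was at most 0.0545.

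Of the 614 shared transcripts, 209 had a higher and 405 a lower mean in SHR+Iso than in SHR. Limma tested 289, of which 122 passed an adjusted p of 0.05, 35 higher and 87 lower, and 204 had an unadjusted p under 0.05. The median log2 difference was 1.29 among those higher and -1.46 among those lower. Among Ensembl transcripts 12 were higher and 26 lower, and among assembled transcripts 23 were higher and 61 lower. The values of the groups did not overlap for 52 of the 614, or 8.47% against 0.216% by chance. These figures and p-values describe a list selected for strain and treatment differences. The balance of directions depended on the scaling: after quantile normalization, 99 transcripts passed, 81 higher and 18 lower, and the median difference of tested transcripts moved by 0.60, from -0.89 to -0.29. That scaling gave all libraries the same distribution over the tested transcripts alone. A list selected for differences need not have 1 distribution, so neither balance can be taken as the right one. The number of calls was 273 without a filter, 44 with a filter at 5, 67 with a pseudocount of 0.1 and 203 in 1 fit over all 3 groups. It was 71, 80 and 186 without SHR+Iso replicates 2, 4 and 6, 56 and 71 without SHR replicates 4 and 5, and 29 without SHR+Iso replicates 2 and 4 together.

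The strain and treatment comparisons were set side by side to ask whether treatment moved transcripts towards the WKY level. Among the 614 shared transcripts, those higher in SHR than in WKY were mostly lower after treatment, and the reverse. The other 3391 of the 4005 had no SHR+Iso value, so their levels after treatment are unknown. The shared transcripts were selected for differences in both comparisons, and these directions follow in part from that selection. Of the 404 shared transcripts higher in SHR, 389 had a lower mean in SHR+Iso than in SHR. Of the 210 lower in SHR, 194 had a higher mean in SHR+Iso. Averaged over the 404, log2(value + 1) was 1.79 ± 0.08 in SHR, 0.80 ± 0.23 in WKY and 0.88 ± 0.28 in SHR+Iso (SD, n = 6). Averaged over the 210, it was 0.71 ± 0.04 in SHR, 1.61 ± 0.11 in WKY and 1.41 ± 0.10 in SHR+Iso (SD, n = 6). Within SHR+Iso, replicates 2 and 4, which had the most transcripts at 0, lay lowest over the 404, at 0.48 and 0.62 against 0.91 to 1.19 in the other 4, and highest over the 210, at 1.55 and 1.52 against 1.31 to 1.40. WKY was split as well, with replicates 1 and 6 nearest to SHR. They lay at 1.07 and 1.06 over the 404, against 0.54 to 0.80 in the other 4. Over the 210 they lay at 1.47 and 1.49, against 1.63 to 1.70.

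**Figure D2:**
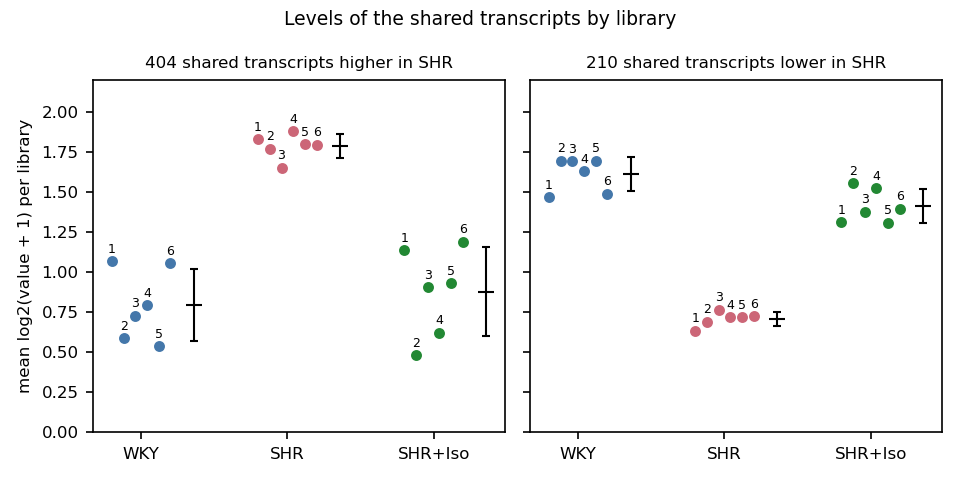
Mean log2(value + 1) per library (vertical axis) over the 404 shared transcripts higher in SHR (left) and the 210 lower in SHR (right), with replicate numbers beside the points and the mean and SD of each group of 6 in black. SHR lies at 1.79 on the left and 0.71 on the right. WKY and SHR+Iso lie near each other and spread more than SHR on the left.

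Limma called 90 of the 265 transcripts tested in both comparisons, 87 of them in opposite directions and 3 in the same direction. Of the 87, 61 were higher in SHR and lower after treatment, where independent lists would give 41.1, and 26 were the reverse, where they would give 7.22. This balance turned round with the scaling: after quantile normalization 68 were opposite, 14 of them higher in SHR and lower after treatment and 54 the reverse. Here too the normalization ran over selected transcripts alone and does not settle the balance. Across the 614 transcripts, which are not independent replicates, the differences had r = -0.81 and a covariance of -0.87. Unchanged groups against the shared SHR libraries gave -0.50 and -0.09, so that the covariances differed by -0.78. Unchanged groups also gave 66.6% opposite directions without any selection of transcripts, where 583 of the 614 were observed. With transcripts selected on p and size in both comparisons, simulated groups with no effect gave 99.2% opposite directions, above the 95.3% observed in the 299 transcripts that met the same criteria, and simulated strain differences with no treatment effect gave 69.5%. The no-effect lists held 233 transcripts on average over 10 pooled simulations each, so only directions are compared here, not numbers. With SHR libraries split between the comparisons, r was -0.69 and -0.72, and 576 and 577 of the 614 were opposite. With 3 SHR libraries in each test, 3 and 1 transcripts were called in opposite directions, where independent lists would give 2.77 and 0.430 higher in SHR and lower after treatment and 0.558 and 0.174 the reverse. Because both lists were selected for differences involving the same SHR libraries, these figures hold selection as well as any effect. The 87 became 206 without a filter, 29 with a filter at 5 and 47 with a pseudocount of 0.1. They became 52, 38 and 50 without SHR replicates 1, 4 and 5, 57 without SHR+Iso replicate 2, and 22 without SHR+Iso replicates 2 and 4 together.

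**Figure D3:**
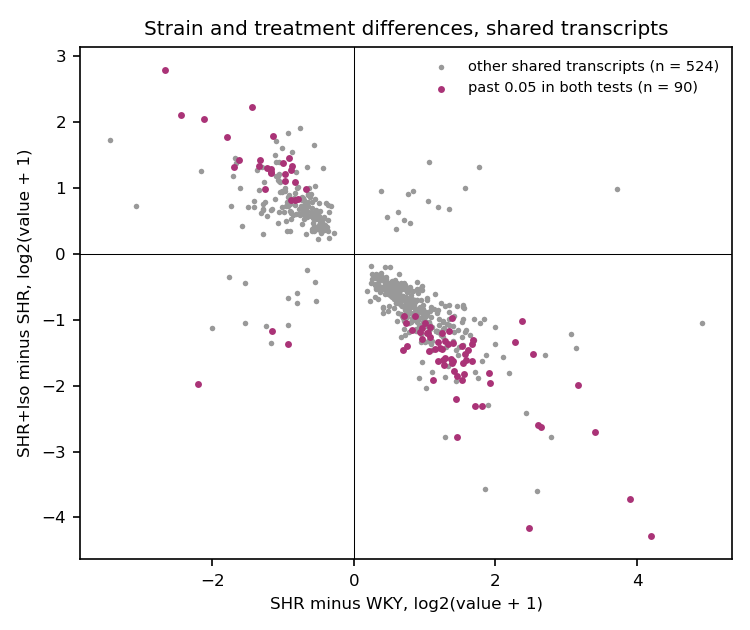
Log2(value + 1) difference of SHR+Iso from SHR (vertical axis) against that of SHR from WKY (horizontal axis) for the 614 shared transcripts, 1 point each. Coloured points are the 90 past an adjusted p of 0.05 in both tests, of which 87 lie in the upper left or lower right.

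Treated SHR were also set against WKY, where strain and treatment differ together. Over the 614 transcripts the median absolute log2 difference was 0.15 between SHR+Iso and WKY, 0.82 between SHR and WKY and 0.79 between SHR+Iso and SHR. Of 255 transcripts tested with limma, 28 passed an adjusted p of 0.05, 12 higher and 16 lower in SHR+Iso, and 35 had an unadjusted p under 0.05. Of these 28, 24 were transcripts whose strain and treatment differences had the same direction, as 31 of the 614 did. The difference from WKY is the sum of the strain and treatment differences. Both were selected for size, so opposite ones cancel and those of the same direction add up. The 24 of 28, the number of calls and the median of 0.15 follow largely from this. The groups did not overlap for 27 of the 614, where chance gives 0.216% of transcripts that were not selected. With a filter at 5 the number of calls was 10. A missed threshold does not show that a transcript had the same level in both groups.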

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

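Chosen only after their results were seen were the test of library components shared between WKY and SHR+Iso, the distance of treated from WKY libraries, the simulations that draw whole libraries, the joint reading of pass share and opposite share, and the comparisons of single treated libraries and of pairs of them. For 6 tests the bound written first would count against the explanation and was not kept, and 4 of these readings were changed with the values known: selected chance values, strain differences alone, lower depth, and the splits for SHR+Iso against WKY. The reading of strain differences alone was changed more than once, for a time on the joint reading.

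The strain and treatment differences had opposite directions in 95.3% of 299 shared transcripts. These had an unadjusted p under 0.05 and a log2 difference of at least 1 in both comparisons. Here p-values came from pooled-variance t-tests on log2(value + 0.01) without a filter, not from limma, and differences were on that scale. Simulated strain differences of the listed sizes with no treatment effect passed at most 4% of strain-listed transcripts against 9.59% observed. They passed up to 16.2% when whole libraries were drawn with replacement, with 9 of 100 at or above the observed value. Their opposite share was 69.5% and with whole libraries 70.6%, at most 100%. By the pass share, strain differences alone stay open where the bound is taken over whole-library draws. Both observed values together were reached by 0 of 100 draws, whole-library or independent. This joint reading, chosen after its value was seen, decides nothing. The simulated SHR values were drawn afresh and did not help choose the strain list, as the real ones did. Strain differences alone therefore stay open. Selected chance values stay open. With no effect 99.2% were opposite, and 17.5% of strain transcripts passed for the treatment. These lists held 233 transcripts on average over 10 pooled simulations. How many transcripts the real lists were chosen from is not known, so the observed 299 cannot be set against that number. The 19.7% with a treatment p under 0.005 exceeded the highest simulated 17.1% by about the binomial standard error of 2.30. It lay below the highest with whole libraries, 29.9%. The first components within WKY and within SHR+Iso libraries had r = 0.45 across the shared transcripts, as a difference between libraries running through those groups may give; the treated component had r = 0.41 with the SHR minus WKY difference and the WKY component -0.35 with SHR+Iso minus SHR, while the SHR component had 0.13 with that of WKY and 0.04 with that of SHR+Iso. A treatment that moved strain differences back stays open, since the median distance of treated from WKY libraries, 0.15, follows largely from the choice of transcripts.

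SHR+Iso replicates 2 and 4 stood apart from the other 4 treated libraries. Of 175 transcripts with a mean of at least 10 in the other 4, 30 (17.1%) were listed at 0 in either, and of 1347 with a mean below 1, 627 (46.5%) were. Singly, replicates 2 and 4 had 10.6% and 10% of the abundant transcripts at 0, against 2.48% to 4% in the other 4, and 41.1% and 37.3% of the low ones, against 16.9% to 27.2%; every library passed the 1% set beforehand as a sign against lower depth, so that bound decides nothing and lower depth stays open. Both lay below the other 4 for 403 transcripts and above them for 366, so that 52.4% went the more common way, which argues against a single scale factor. No other pair exceeded 542 such transcripts, and no biological explanation was tested.

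MERGE.26395.1 had a value of 8.43 in SHR replicate 6, above the other 5 SHR libraries, which lay close together at 6.39 to 6.80. The same transcript had 1.07 in SHR+Iso replicate 6, far above the other 5 treated libraries. These were 2 of 25 groups of libraries checked, and chance marks about 1 in 20.

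Other splits of the 12 libraries were drawn 100 times per comparison, the real split included. For SHR against WKY, 1 of 100 gave as many calls as the real 1368, and the highest other gave 348. For SHR+Iso against SHR, 1 of 100 reached 122, and the highest other gave 17. For SHR+Iso against WKY, 1 of 100 reached 28, and the highest other gave 4. The transcripts were selected on the real groups, which fixes these outcomes, and chance can be neither excluded nor upheld from them.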

How the results depend on the processing

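Leaving out SHR+Iso replicates 2 and 4 together was chosen after seeing the data. For SHR against WKY (1368 calls), the number was 3102 without a filter, 404 with a filter at 5 and 213 in 1 fit over all 3 groups, and 1198 to 1315 when each library was left out in turn. For SHR+Iso against SHR (122), it was 273 without a filter, 44 at 5, 67 with a pseudocount of 0.1, 203 over all 3 groups, 29 without SHR+Iso replicates 2 and 4, and 56 to 186 leaving out each library. For SHR+Iso against WKY (28), it was 10 at 5 and 25 to 28 leaving out each library. For opposite directions (87), it was 206 without a filter, 29 at 5, 47 with a pseudocount of 0.1, 22 without SHR+Iso replicates 2 and 4, 3 and 1 with SHR split, and 38 to 125 leaving out each library. Filters and the fit over all 3 groups change the number of transcripts tested. The SHR split left 3 SHR libraries per test. Of 265 transcripts, 4 were then called higher and 15 lower after treatment in 1 split, and 1 and 2 in the other, against 29 and 85. Over the 614 shared transcripts, 576 and 577 stayed opposite. For the pseudocount and the left-out libraries the cause was not tested; sample size alone does not give it, since calls rose to 175 and 186 without SHR+Iso replicates 1 and 6. Leaving out each pair of treated libraries, also chosen after seeing the data, gave 29 (replicates 2 and 4) to 204 (replicates 1 and 6). Of the 29 calls without replicates 2 and 4, 24 were also among the 122; after quantile normalization, 53 of 99 were. Of the 8 named transcripts, 7 passed under every setting run, and ENSRNOT00000027630 did not without SHR+Iso replicates 2 and 4.

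With the replicate number as a block, 1316, 127 and 24 transcripts passed in the 3 comparisons and 87 had opposite directions. Deviations of same-numbered libraries had r from -0.04 to 0.07 for SHR and WKY and -0.04 to 0.05 for SHR+Iso and SHR. For SHR+Iso and WKY r was -0.09 to 0.23, over 0.1 for 3 of the 6 numbers, while libraries with different numbers had -0.28 to 0.30 and 1 of 6 correlated best with its own number. Not every pair passed 0.1 in any comparison, and the numbers were not taken as pairs. DESeq2 and voom alternatives need counts and were not run, and the gene list alternatives were not run because no symbol matched. Depth is unknown and limits what a value of 0 shows.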

Other observations

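Assembled transcripts of the same locus tended to differ between the strains in the same direction. Of 394 loci with at least 2 listed transcripts, 166 (42.1%) held members both higher and lower in SHR, where shuffled directions gave 241 on average and 223 to 258 in the central 95%. The permutation p was 2e-04, the smallest that 10000 shuffles give. The hypothesis under test was that transcripts of a locus exchange with each other more often than by chance, and the result went the opposite way. Among transcripts past the threshold, 42 of 96 such loci held both directions, where shuffling gave 57.1 on average. Locus membership was read from the IDs, and transcripts that share reads are not independent.

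The SHR+Iso libraries listed 2209 transcripts with no WKY or SHR values analysed here, so no comparison was made for them. Of these, 1175 were above 0 in all 6 libraries and 132 were listed at 0 in all 6. Their median mean was 0.931, 130 had a mean of at least 10, and the highest mean was 358.5.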
